A study of Mus musculus with 3 samples.

How the data were processed

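Gene expression was measured in 3 libraries of RNA labelled as from the colon of untreated wild-type mice, at day 0 by their titles. 2 libraries are labelled mature macrophages and carry the numbers 1 and 3, and 1 is labelled monocytes and immature macrophages and carries the number 3. Total RNA was extracted with Trizol and sequenced from the 3' ends of transcripts with a Lexogen QuantSeq kit, per the labels' protocols. The submitters' processing notes name Bowtie2 and bedtools without versions and the human build hg19. The symbols in the files are nevertheless mouse symbols: 99.54% of the 23238 different symbols match a current or older symbol of the mouse RefSeq annotation of GRCm38.p6, which was used for names only. No coordinates are given, because the build named and the symbols belong to different species. The counting tool, the handling of reads with several matches and the normalization are not given in the sources used here.

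Each deposited file holds 23282 rows with a gene symbol and a value on a log2 scale. The base and the added number were read from the values: with base 2 and an added 1, the low values unlogged to whole multiples of 1 step per library, within a tolerance of 0.1 steps, for 95.5% and 97.9% of the low values in mature macrophage libraries 1 and 3 and for 89.0% in the library labelled monocytes and immature macrophages. The value of 1 read was 0.774, 1.502 and 1.796 in the same order, and dividing by it gave the reads quoted here, which are recovered values and no counts of the authors. In mature macrophage library 3 and the library labelled monocytes and immature macrophages, 9785 and 8859 rows hold values above 0 but under 1 read, so the values are not plain counts. Mature macrophage library 1 holds 0 such rows. It lists 19464 rows at an exact 0, against 8778 and 7503 in those libraries, for a reason that is not given. An exact 0 was not read as absence. Cox4i1, a respiratory chain gene, is listed at 0 in mature macrophage library 1, at 11.45 in library 3 and at 3.75 in the library labelled monocytes and immature macrophages. Whether such a 0 is a failed estimate or a gene without reads cannot be told from the values. 35 symbols listed more than once, in 79 rows, were left out, which left 23203.

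A count-based test had been planned for the case of deposited counts. The log2 unit rules it out, and the stated fallback was used: limma 3.58.1 in R 4.3.3 on the deposited log2(value + 1) values, with a variance trend and no further normalization, 1 library against 2. P-values are two-sided and Benjamini-Hochberg adjusted, and a gene was called at an adjusted p under 0.05. Genes with a value of at least 5 in at least 1 library were tested, which gave 5293 genes; this level, also used for "detected", was chosen after the values had been seen. The design has 1 residual degree of freedom, from the pair of mature macrophage libraries, and the lone library is assumed to vary as they do. The labels do not say that the libraries come from separate animals, so p-values measure only the spread between these samples, which may be technical.

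The 33 gene lists were fixed before the data were examined. Of these, 28 had at least 3 tested members and were tested with limma's camera at a preset inter-gene correlation of 0.01. The correlation was also estimated per list, a version that rests on the 1 residual degree of freedom and could hardly call any list. The median difference of each list was set among 10000 random lists of the same size matched on mean expression in 20 bins. 8 further lists were written after the values had been seen and were not tested with camera; they describe the content of the libraries and enter the tests of explanations in the closing section. Genes to be named were fixed by rule: the 12 highest and 12 lowest called genes with a log2 mean CPM of at least 5 and a value beyond both mature macrophage libraries, filled up with uncalled genes given as values, then the 3 members of each list with the largest differences at a log2 mean CPM of at least 4, and a fixed set of 20 monocyte and macrophage genes. Predicted, ribosomal, mitochondrial and antigen receptor genes were passed over in the first part. Some genes that the rule names are not reported here.

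The fit was tested on simulated data in 100 draws per setting, 1 library against 2, with 200 genes changed. The changed genes were drawn only from those with more than 300 expected reads, so recovery does not cover weaker genes. At a dispersion of 0.1 and 3671 genes tested, 64-fold changes were recovered in 87.1% of changed genes. At the same dispersion and 3715 genes tested, 8-fold changes were recovered in 0.0%, although the sign was right in 100.0%. With a dispersion of 0.01, 36.2% of 64-fold and 0.0% of 8-fold changes were recovered. When each library was drawn from 8402 RNA molecules and then amplified, recovery was 1.4% for 64-fold and 0.0% for 8-fold changes, and with no gene changed 8 of 100 draws still gave calls, up to 280 genes. With 64-fold changes, 4 of 100 draws gave calls, up to 1306 genes, and at most 1232 of the calls in a draw were of unchanged genes. The settings other than the 8-fold ones at dispersion 0.1 and from few molecules, and the unchanged one from few molecules, were added after the first 10 draws of those had recovered no changed gene.

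Alternatives were other scalings, filters, added numbers, thinning, a test against a log2 difference of 1, and leaving out each mature macrophage library. The setting named no filter still required at least 1 read in at least 1 library. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6.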

Results

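The series holds 3 transcript profiles labelled as cells from the colon of untreated wild-type mice, of which 1 is labelled monocytes and immature macrophages and 2 mature macrophages. The mature macrophage libraries held 4353049 and 5090064 recovered reads, and the library labelled monocytes and immature macrophages 5453764. A gene was called detected at a log2 value of at least 5, and 3 reads correspond to log2 values of 1.73, 2.46 and 2.68 in the same order. By this level 2594, 2010 and 2685 of the 23203 genes used were detected. Rn45s, the ribosomal RNA precursor, took 11.7%, 9.9% and 11.8% of the totals. Values of single genes are given for each library, without mean or SD, because what an exact 0 stands for is not known. Reads copied by PCR are not independent molecules, so neither the floors nor the values give a counting error.

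The comparison of the library labelled monocytes and immature macrophages with the mature macrophages asks which genes separate these populations in the colon. Mbp and Nrgn led the genes called higher in it. Mbp, a myelin protein, had a log2 value of 15.48 against 0.83 and 0.01 in mature macrophage libraries 1 and 3, and Nrgn, a postsynaptic calmodulin-binding protein, 14.64 against 0 and 0.01. C1qa, a subunit of complement C1q called lower, had log2 values of 13.38 and 13.45 in the mature macrophages and 1.48 in the other library. Because its content went against its label, this library is named by its label throughout.

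By limma, 1168 of 5293 genes were called higher in the library labelled monocytes and immature macrophages and 7 were called lower, with 1674 at an unadjusted p under 0.05. Of the 1168, 1115 lay under 1 read in both mature macrophage libraries and 2 were detected in both. The spread of the lone library was not measured and is taken from the mature macrophages; in simulated libraries of few molecules with no gene changed and 3072 genes tested, up to 280 genes were called, and with 200 genes changed 64-fold and 2938 tested, up to 1232 unchanged genes were called. With at least 10 reads required in at least 2 libraries, the numbers were 4 higher and 16 lower of 1721 genes. With no filter beyond 1 read in at least 1 library, they were 3249 higher and 75 lower of 9402. Of the 4 and 16 genes, 1 and 5 were among the 1168 and 7.

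The other genes that led the called ones were Nme7, Kif1b, Gnao1, Camk2n1, Ttyh1, Epb4.1l1, Ndrg4, Ndufa4, Nsg2 and Gpm6b. Their log2 values in the library labelled monocytes and immature macrophages ran from 14.21 for Gpm6b to 14.9 for Camk2n1. In mature macrophage library 1 they were listed at 0, apart from Camk2n1 at 0.83, and in library 3 none exceeded 0.014. Gnao1 encodes a G protein subunit abundant in neurons, and Ndufa4 a respiratory chain protein found in most cells. Adjusted p was 0.0466 for Mbp and 0.0464 for Camk2n1, and it ran from 0.0194 to 0.0207 for the rest with Nrgn. Scaled by library totals only, the calls of Mbp and Camk2n1 ended, at adjusted p of 0.0818 and 0.0832. Their log2 differences were then 14.29 and 13.71, against 15.06 and 14.48 as deposited.

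5 genes that met the naming rule were called lower. Cxcl2, a neutrophil-attracting chemokine, had log2 values of 13.67 and 14.19 in the mature macrophages and 0.03 in the library labelled monocytes and immature macrophages, with an adjusted p of 0.0478. Socs3, a feedback inhibitor of cytokine signalling, had 13.39, 13.41 and 0.03, with an adjusted p of 0.0489. Cd74, the invariant chain of MHC class II, had 14.51, 15.19 and 3.02, with an adjusted p of 0.0406. For C1qa adjusted p was 0.0472, and for Tmem176b, at 13.46, 13.89 and 3.02, it was 0.047. With median-of-ratios size factors all 5 calls ended, at adjusted p from 0.0709 for Socs3 to 0.0977 for Tmem176b, and with library totals only those of C1qa and Socs3 ended, at 0.0685 and 0.0681. The log2 differences with median-of-ratios size factors were -13.45 for Cxcl2, -12.92 for Socs3, -10.86 for C1qa, -10.58 for Cd74 and -9.4 for Tmem176b. As deposited they were -13.9, -13.37, -11.94, -11.83 and -10.66 in the same order. Genes of the same direction that did not pass were H2-Ab1, at 14.86, 15.92 and 1.48 with an adjusted p of 0.0513, and Rgs1, at 12.34, 12.74 and 0.03 with an adjusted p of 0.0667. Laptm5, H2-DMb1, Fosb, Fcer1g and Pf4 were detected in both mature macrophage libraries and had 0.03 in the other library, with adjusted p from 0.0958 to 0.146.

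Among the monocyte and macrophage genes fixed beforehand, Csf1r, the receptor for the growth factor of macrophages, had log2 values of 12.57 and 12.83 in the mature macrophages and 2.67 in the library labelled monocytes and immature macrophages, with an adjusted p of 0.0638. The fractalkine receptor Cx3cr1 had 12.1, 12.86 and 1.48, and the integrin Itgam 10.96, 11.43 and 0.03. Il1b had 12.73, 11.67 and 2.19. H2-Aa was detected in every library, at 15.82, 16.34 and 11.22. The monocyte marker Ly6c2 was at 0.83, 0.01 and 0.03, so it reached no more than 1 read in any library, and Mertk was likewise at or under 0.014. Ptprc, which encodes CD45, was at 2.85, 2 and 0.03. Ccr2, the chemokine receptor of classical monocytes, was at 10.87 in mature macrophage library 1, 2.8 in library 3 and 0.03 in the library labelled monocytes and immature macrophages. Several macrophage genes also differed between the mature macrophage libraries: Adgre1, an adhesion receptor of macrophages, was at 0.83 and 10.33, Cd68 at 11.51 and 1.32, and Mrc1 at 11 and 4.35, against 1.48, 2.19 and 3.55 in the other library. Cd14 was at 3.66, 7.55 and 1.48. Fcgr1, Cd163, Il10 and Tnf were detected in mature macrophage library 1, at 7.92, 5.93, 6.77 and 5.91, and had 0.01 in library 3.

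Of 9 measured glial and neuronal markers, 7 were detected in the library labelled monocytes and immature macrophages, 0 and 1 in the mature macrophages, and 4 were called higher, or 6 adjusted over the list alone. Snap25, a synaptic vesicle fusion protein, was at 12.71 and Gfap, an intermediate filament of glia, at 12.11, against 0 to 0.014 in the mature macrophages. The list was called higher by camera at an adjusted p of 0.0057, and its median difference stood at percentile 98.79 of the random lists. Its 7 tested members were all detected in the library labelled monocytes and immature macrophages, and nearly all passed the filter only through it. The gene calls were therefore largely fixed in advance. The camera result and the percentile rest on the same members and are no separate support for the numbers detected. With an estimated correlation the adjusted p was 0.546, and with at least 10 reads required in at least 2 libraries the list had too few genes left for a test.

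**Figure D1:**
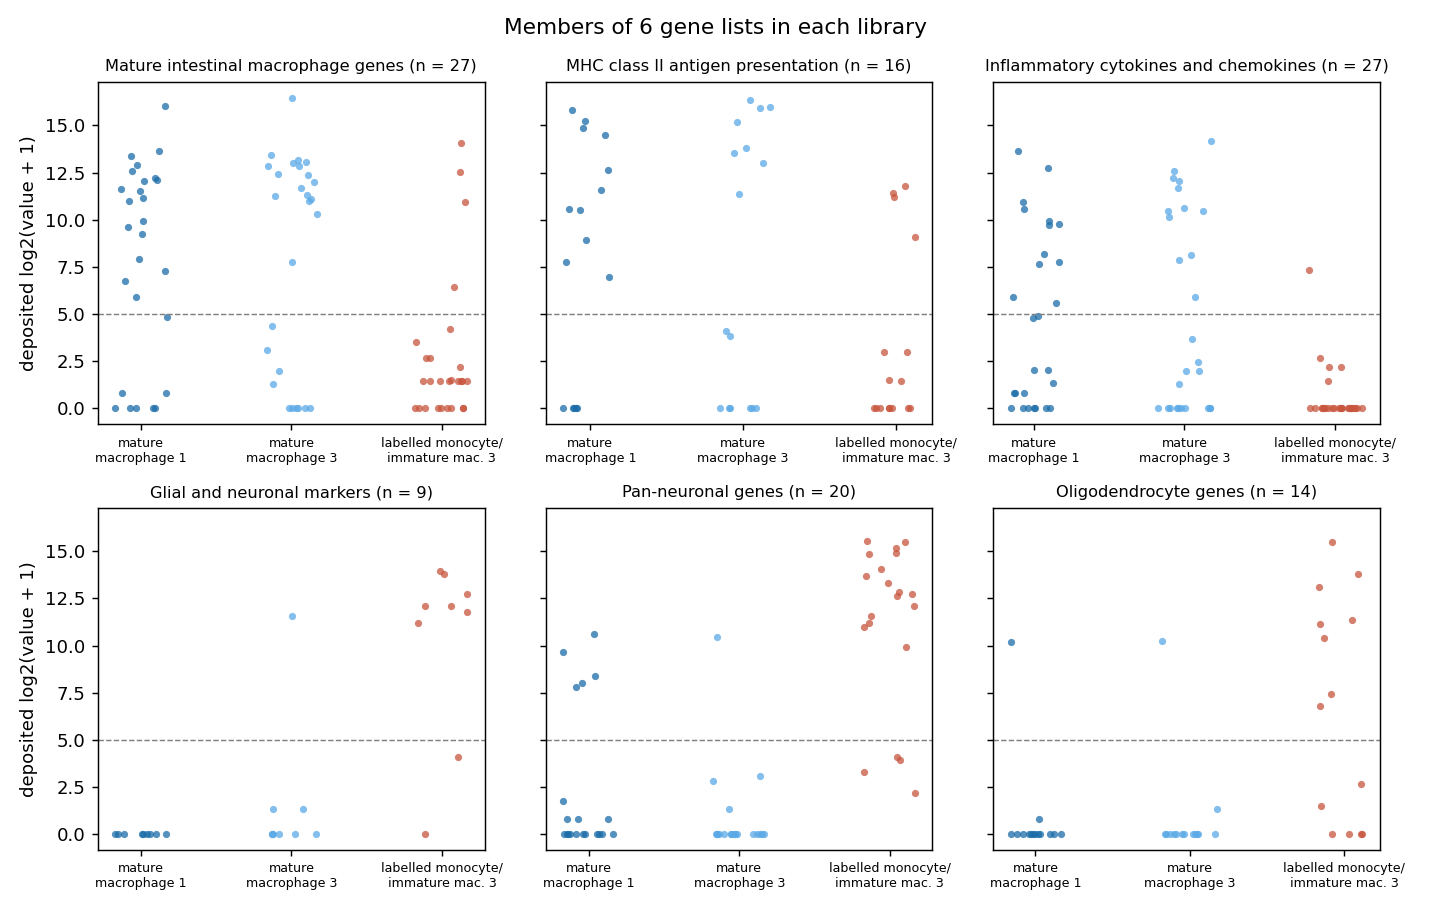
Deposited log2(value + 1) of each member of 6 gene lists, with 1 point per gene, in mature macrophage libraries 1 and 3 and in the library labelled monocytes and immature macrophages; the dashed line is the detection level of 5. Of the glial and neuronal markers 0, 1 and 7 lie at or above the line, and of the mature intestinal macrophage genes 19, 17 and 4. The pan-neuronal and oligodendrocyte lists were written after the values had been seen.

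Camera called 16 of the 28 tested lists lower in the library labelled monocytes and immature macrophages relative to the other genes. Those other genes include the 1115 that lay under 1 read in both mature macrophage libraries and were called higher. A list can therefore rank lower without lower values, as the uncalled glycolysis list did with a median difference of 0.89. With an estimated correlation no list was called, and adjusted p was at least 0.493. That version rests on 1 residual degree of freedom, so its lack of calls argues neither for nor against a list. Of 27 mature intestinal macrophage genes, 19 and 17 were detected in the mature macrophages and 4 in the other library, at an adjusted p of 1.65e-05. 1 member, C1qa, was called lower and none adjusted over the list alone. Of 16 MHC class II genes, 11, 8 and 4 were detected, at an adjusted p of 0.000177. Of 27 inflammatory cytokines and chemokines 12, 12 and 1 were detected, at an adjusted p of 6.62e-05. Of 20 classical monocyte genes, which would mark the population named on the label, 8, 5 and 2 were detected, at an adjusted p of 0.00378. Each of these 4 lists had an adjusted p of 0.493 with an estimated correlation.

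Of 84 ribosomal protein genes, 75, 73 and 56 were detected, at an adjusted p of 1.45e-06, and of 22 immediate early and heat shock genes, which respond to cell handling, 19, 17 and 6, at an adjusted p of 1.65e-05; both had 0.493 with an estimated correlation, and no ribosomal protein gene was called. With at least 10 reads required in at least 2 libraries, camera gave the ribosomal protein list an adjusted p of 0.0165. Of 52 oxidative phosphorylation genes, 26, 21 and 31 were detected, and the list was not called, at an adjusted p of 0.974. The median difference of all tested genes was -1.1 on the log2 scale as deposited, 0.1 with median-of-ratios size factors and -1.9 with library totals only. Relative to it, the ribosomal protein genes had a median of -0.63, -0.49 and -0.78 in the same order, and the oxidative phosphorylation genes 3.03, 2.97 and 2.95.

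Markers of other colon cells were present in the mature macrophage libraries. Of 27 colon epithelial markers, 10, 7 and 1 were detected, and Lypd8 was at 10.02, 11.35 and 0.03. The list was called lower at an adjusted p of 0.0131, or not called at 0.493 with an estimated correlation and at 0.268 with at least 10 reads required in at least 2 libraries. Of 15 fibroblast and smooth muscle markers, 8, 6 and 5 were detected; the collagen gene Col1a2 was at 11.14, 15.11 and 7.09, and the list was called lower at an adjusted p of 0.0343, or 0.493 with an estimated correlation. None of the 12 endothelial markers was detected in any library.

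The comparison of the mature macrophage libraries with each other asks how far libraries of the same label resemble one another. Only library 3 holds values above 0 but under 1 read. Whether both were processed alike is not known, which limits this comparison. They shared 906 detected genes, against 224.7 for independent sets, which was 34.9% of those in library 1 and 45.1% of those in library 3. With the library labelled monocytes and immature macrophages, library 1 shared 824, against 300.2 for independent sets, and library 3 shared 691, against 232.6. Clec4n, a pattern recognition receptor, was listed at 0 in library 1 and was at 12.66 in library 3, while Clec10a was at 11.07 and 1.32. Of 1730 genes with at least 500 reads in library 1, 928 had at most 3 in library 3, and of 1608 in library 3, 803 had at most 3 in library 1. Across the 5293 genes, which are not independent replicates, Pearson's r was 0.053 and Spearman's rho 0.202 between the mature macrophage libraries. These coefficients were -0.285 and -0.227 between library 1 and the library labelled monocytes and immature macrophages, and -0.194 and -0.174 for library 3. The filter left out genes low in every library. It kept 1289, 838 and 1595 genes detected only in library 1, in library 3 and in the library labelled monocytes and immature macrophages. Such a filter lowers the coefficients. With no filter beyond 1 read in at least 1 library, 9402 genes remained. Pearson's r was then 0.269 between the mature macrophage libraries. It turned positive with the library labelled monocytes and immature macrophages, at 0.055 and 0.072, while Spearman's rho was 0.3, -0.03 and -0.032.

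**Figure D2:**
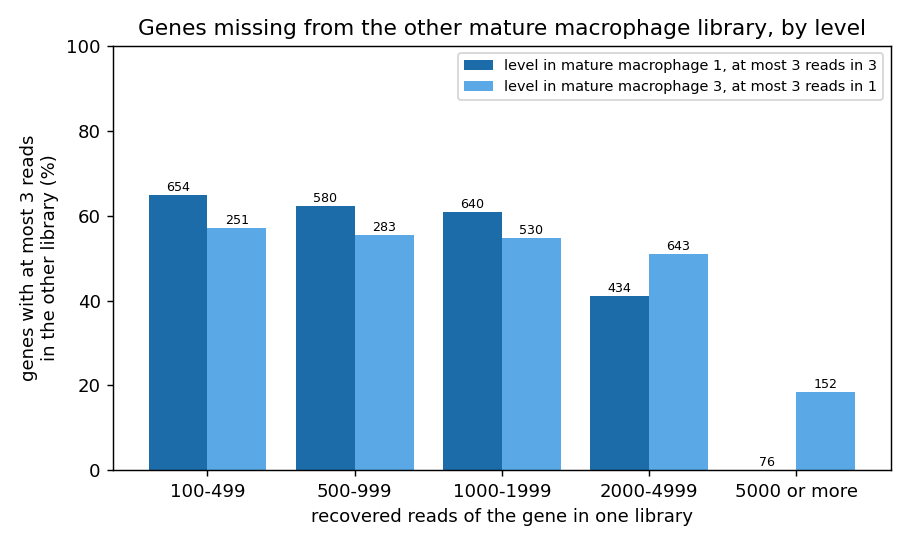
Percent of genes with at most 3 recovered reads in one mature macrophage library, by their reads in the other; numbers above the bars are genes per class. The share was 64.8% at 100 to under 500 reads and 0.0% at 5000 or more reads in library 1, and 57.0% and 18.4% by level in library 3.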

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

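The added numbers of 32, the values under 1 read set to 0 and the fit with no variance trend were chosen after seeing the data. So were the list tests on library totals and the correlations with no filter. No paired analysis was possible because only 1 WT number is in both groups. Leaving out either mature macrophage library left no residual degrees of freedom, so those are values with no test. The planned count-based fits were not run, since the values are not counts. With 1 residual degree of freedom, 8-fold changes were recovered in 0.0% of changed genes in the simulated data. The causes were not tested, except that a stricter filter removes the genes under 1 read in both mature macrophage libraries.

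Genes called higher numbered 3249 with no filter and 4 with at least 10 reads in at least 2 libraries, against 1168; the other settings stayed within 1.5 times. Genes called lower, 7 as reported, numbered 3 with median-of-ratios size factors, 15 with library totals only, 75 with no filter, 16 with at least 10 reads in at least 2 libraries, 14 when thinned, 52 with an added number of 32 and 68 with no variance trend. Lists called went from 1 higher and 16 lower to 0 and 0 with an estimated correlation, a version that could hardly call any list with 1 residual degree of freedom. With at least 10 reads in at least 2 libraries 14 of 20 tested lists were called lower; the colon epithelial list lost its call at an adjusted p of 0.268, the only list called higher was the erythroid one, at 0.0214, and the glial and neuronal and the non-classical monocyte lists could not be tested. With an added number of 32, 14 of 28 were called lower. The correlation of the mature macrophage libraries was -0.064 (Pearson) and 0.126 (Spearman) with at least 10 reads in at least 2 libraries, and 0.269 and 0.3 with no filter, or 0.269 and 0.239 with values under 1 read also set to 0. The only T, NK and innate lymphoid marker detected in the library labelled monocytes and immature macrophages fell to 0 detected with library totals only. Among the named genes no direction reversed under another scaling, filter or added number. With at least 10 reads in at least 2 libraries only 65 of the 110 named genes could be compared. Without mature macrophage replicate 1 or 3 the sign of 5 each turned, none of them called. Among them were Cd68, from -4.22 to 0.87, and Adgre1, from -4.1 to 0.66. 13 values lost their call and 74 gained one.

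With median-of-ratios size factors, median differences moved to -3.87 for mature intestinal macrophage genes, -0.48 for lipid handling, 3.07 for oxidative phosphorylation, -7.93 for immediate early genes, -0.39 for ribosomal proteins, -3.16 for neutrophil, -2.16 for dendritic cell, 13.01 for glial and neuronal and 4.52 for erythroid markers. With library totals only they were -5.03 for mature intestinal macrophage genes, -2.29 for lipid handling, 1.05 for oxidative phosphorylation, -10.02 for immediate early genes, -2.68 for ribosomal proteins, -4.95 for neutrophil, -4.03 for colon epithelial, 11.61 for glial and neuronal and 2.23 for erythroid markers. Thinned, they were -5.52 for mature intestinal macrophage genes, -1.47 for lipid handling, -9.93 for immediate early genes, -6.07 for neutrophil and 11.79 for glial and neuronal markers. The glycolysis median, 0.89 as reported, was 2.23 with median-of-ratios size factors and changed sign to -0.06 with library totals only.

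Without mature macrophage replicate 1 or 3, medians ran from -7.85 to -6.5 for classical monocyte genes, -7.76 to -7.28 for mature intestinal macrophage genes, -6.34 to -3.15 for efferocytosis, -7.55 to -4.53 for MHC class II, -10.11 to -7.07 for cytokines and chemokines, -9 to -7.27 for NF-kB feedback, -8.63 to -7.08 for the IL-10 and TGF-beta axis, -7.74 to -6.07 for pattern recognition receptors, -0.67 to -0.67 for lipid handling, -1.34 to 1.48 for glycolysis, -6.98 to -3.79 for matrix remodelling, -2.44 to -1.48 for ribosomal proteins, -6.7 to -6.56 for neutrophil, -6.24 to -5.69 for colon epithelial, 12.1 to 12.11 for glial and neuronal and 1.49 to 2.58 for erythroid markers. They ran from -7.45 to -0.8 for self-maintaining macrophage genes, -8.17 to -2.56 for non-classical monocyte genes, -8.43 to -1.3 for interferon-stimulated genes, -8.36 to -2.51 for chemotactic receptors, -9.74 to -1.93 for the cell cycle, -7.28 to -3.13 for myeloid transcription factors, -4.83 to -2.38 for lysosomal genes and -4.57 to -2.42 for fibroblast and smooth muscle markers. The reported medians lay outside these ranges for mature intestinal macrophage genes (-4.29), lipid handling (-1.48), MHC class II (-4.46), NF-kB feedback (-5.68), the IL-10 and TGF-beta axis (-5.17) and neutrophil (-4.19), colon epithelial (-3.5) and erythroid (3.18) markers. Uncalled T, NK and innate lymphoid markers changed sign, from -5.39 to 0.02, as did the 2 B and plasma cell markers, too few for a list test, from -0.2 to 3.71.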

Other observations

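All tests of explanations below, and the 8 added gene lists, were chosen after the values had been seen. In the library labelled monocytes and immature macrophages, 12 of 18 genes of central excitatory neurons were detected, 6 of 8 of inhibitory neurons, 16 of 20 pan-neuronal, 8 of 14 of oligodendrocytes and 8 of 12 of astrocytes. Mature macrophage libraries 1 and 3 had 1 and 1, 0 and 1, 5 and 1, 1 and 1, and 2 and 3 detected in the same order. Gad2, which makes the transmitter GABA, was at 12.63, Camk2a at 12.37 and the glutamate transporter Slc1a2 at 13.66, each at or under 0.014 in the mature macrophages. Several genes of the same cells, among them Neurod2, Mobp and Aqp4, were at or under 0.03 in the library labelled monocytes and immature macrophages. Of 12 microglia genes, 6, 6 and 2 were detected in mature macrophage libraries 1 and 3 and in that library.

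The nervous system transcripts in the library labelled monocytes and immature macrophages were set against 3 explanations. RNA of enteric neurons and glia, which live in the colon wall, stays open as a source. The share of enteric genes detected was 11.1%, or 23.3% with genes added that central neurons share. Of the glial and neuronal markers fixed beforehand 77.8% were detected. The enteric list and the added genes were chosen after the values had been seen, so the low share cannot decide against this source. Of 18 enteric genes the 2 detected were Phox2a, called higher at 10.1, and Gfra2, at 11.1 here and 12.18 in mature macrophage library 3. The classical monocyte genes, a list fixed beforehand, go against monocytes and immature macrophages as the main source. Of these 20 genes, 2 were detected in this library, against 8 and 5 in mature macrophage libraries 1 and 3. They cannot exclude this source, since many genes were also missing between the mature macrophage libraries. Of 27 mature intestinal macrophage genes, 4 were detected, against 19 and 17. That list marks mature cells, so its low number does not argue against cells labelled immature. The 12.5% of pan-leukocyte genes detected, against 87.5% and 58.3% in the mature macrophages, come from a list written after the values had been seen. A library of nervous tissue under this label stays open as a candidate explanation: the central gene lists were written after the values had been seen, so the 62.5% of them detected, without the genes named by rule or fixed beforehand, cannot support it. A smaller share of myeloid RNA stays open, since H2-Aa, Ctss and Plac8 were at 11.22, 11.81 and 10.75.

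Of the genes with at least 500 reads in mature macrophage library 1, 928 had at most 3 in library 3. Of oxidative phosphorylation genes, which most cells use, with at least 100 reads in one library, 36.4% had at most 3 in the other. The share was 28.6% for lysosomal genes and 7.8% for ribosomal protein genes, which most cells also use. The oxidative phosphorylation share goes against different cells as the whole cause, and the ribosomal share does not. The limits were set after the values had been seen, so this test cannot decide. Few RNA molecules sampled before amplification may contribute and stay open: the share missing from the other library fell to 0.0% at 5000 or more reads in library 1, but only to 18.4% in library 3. Part or all of the difference may still come from different cells.

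The excess of genes called higher over lower goes with the spread of the mature macrophages. Of the 1115 genes tested with both of these libraries under 1 read, 100% were called, against 2% of 150 genes detected in both and under 1 read in the library labelled monocytes and immature macrophages. The 100% was fixed in advance and is no separate test. Such a gene passed the filter only with a value of at least 5 in the library labelled monocytes and immature macrophages, over a near-zero spread. So 1115 of the 1168 genes called higher rest on a near-zero spread of values under 1 read. Of the 3 splits of the libraries into 1 and 2, only 1 gave as many calls, 1175 with the highest other at 0, and 3 splits are too few for a share under 0.05.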
